A study of Homo sapiens with 2 samples.

How the data were processed

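Gene expression was measured by RNA-seq in 2 libraries of Kasumi-1 cells, 1 treated with CP5322 and 1 labelled control. Groups were taken from the treatment label of each sample, and table columns were matched to samples by the sample titles. Per the labels' protocols, cells were flash frozen, RNA was extracted with Trizol, and libraries were made from 2 ug of total RNA with an NEBNext Ultra RNA kit for Illumina, a kit that does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Per the submitters' processing notes, Bowtie 0.12.2 was used. The counter, the genome build and the tool of the authors' comparison are not given in the sources used here.

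The first of the tables used, per the file headers, holds deposited raw counts per gene of each library. It also holds normalized values by the authors, which equal CPM, counts scaled to the library total, with a count of 0 set to a small value above 0. Beside them stand the authors' fold change, which is the ratio of these normalized values, its log2 value, and the authors' p-value and adjusted p-value. The log2 fold recomputed from the deposited normalized values differed from the deposited one by at most 2.46e-08. The second table holds FPKM values by the authors for 33835 genes. Count per FPKM stood in 1 constant ratio between the libraries (1.006 for every gene with counts in both), so FPKM carries the same information with another scale per gene. The count table has 21113 rows. The 12722 genes found only in the FPKM table had a value above 0 in at most 1 library (2384 with CP5322, 2787 in control, 0 in both) and were not used. Values rest on the authors' alignment and counting; how reads that fit several genes were treated is not given in the sources used here, which affects gene families with near-identical copies such as keratins and HLA genes.

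Gene names came from the count table. There, 19 symbols stood as dates and were restored by gene ID. The 138 rows that share a symbol with another row were summed, giving 21000 symbols. Of the gene IDs, 21041 were in GENCODE release 29 (GRCh38), and 96.1% of these had identical chromosome, start and end, so coordinates are given as GRCh38.

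Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), with factors of 0.9998 for CP5322 and 1.0002 for control. Log2 folds are of TMM-scaled CPM with a pseudocount of 1 CPM, and genes needed 1 CPM in at least 1 library. This pseudocount draws the folds of low genes toward 0. Named genes are also given as the plain ratio of scaled CPM, with a 95% exact Clopper-Pearson interval on the share of the summed counts. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules, and they are not adjusted for the number of genes. A count of 0 was taken as 3 counts for a lower bound of a fold. With 1 library per group no test between conditions was possible, and genes were counted by size (2-fold and 4-fold).

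The 46 gene lists were fixed before the data were examined. Of their 1384 entries, 1251 matched a symbol in the count table. For each list, the median log2 fold of members past 1 CPM was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. A list was said to stand apart under percentile 1 or over 99 with at least 5 members. Named genes were the 12 highest and 12 lowest log2 folds among symbols with at least 5 CPM in a library, leaving out clone and LOC names, ribosomal, snRNA, miRNA and pseudogene symbols, XIST and Y-linked genes. Up to 4 members per list with the largest absolute log2 fold were added, and RUNX1, RUNX1T1, KIT, MYC, CD34, ITGAM, CD14, CDKN1A and CSF1R whatever their values.

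The steps were tested on simulated data drawn from the real gene means and library sizes. Among 13628 genes past 1 CPM, 200 genes with a mean of at least 5 CPM were changed. Of these, 100% of the genes changed 3-fold and 100% of those changed 4-fold were called at least 2-fold in the right direction. The counting intervals held 95% of their true folds. This share was fixed in advance, since the simulated counts carried only the counting noise that such intervals assume. Recovery of genes between 1 and 5 CPM, whose folds the pseudocount draws toward 0, was not tested. With no changed gene, 1% of 200 random lists of 20 genes stood apart. A low share was fixed by the design, since these lists and those they were ranked among came from the same genes. It gives no rate of false calls for real lists, whose genes may vary together. All 10 lists raised by 0.3 on the log2 scale, also made of genes with a mean of at least 5 CPM, were found. Recovery of genes and lists may be lower in real libraries, which differ by more than counting noise.

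The alternatives set before the data were examined were pseudocounts of 0.1 and 5, a minimum of 5 CPM or none, median-of-ratios scaling and scaling by the total, protein-coding genes only, rows not summed, FPKM, unmatched random lists, 10 bins, and an adjusted p under 0.01 for the authors' calls. Added after seeing the data were random lists matched on expression, GC content and gene length (4 bins each, from GENCODE 29), counts of genes without matrix, keratin, epidermis, desmosome and immunoglobulin annotation, and counts of genes with over 5 counts in both libraries. Gene ontology terms in the authors' deposited table with 10 to 150 members past 1 CPM were placed among random lists in the same way. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.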

Results

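Kasumi-1, a human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion, was profiled by RNA-seq with and without the compound CP5322. The comparison asks how the treated transcriptome differs from that of the control. One library was made from each condition, so no difference below has a replicate check and no p-value was computed. The dose and the time of exposure are not given in the sources used here. The CP5322 library held 17196985 gene counts and the control library 17093815, and 20696 and 20905 gene symbols had at least 1 count. Values were set side by side as CPM (counts scaled to the library size) after TMM scaling. Each ratio of named genes is given with its 95% exact counting interval, which covers counting error only, not the spread between cultures. A count of 0 allows up to 0.174 CPM in the CP5322 library and 0.175 CPM in control, which is 3 counts.

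With a pseudocount of 1 CPM, few genes differed at least 2-fold between the 2 libraries, while smaller differences beyond counting error were found in many. Counting intervals lay wholly below a ratio of 1 for 20.9% of genes past 1 CPM and wholly above for 18.4%. The group that differed most consisted of collagen and keratin genes found in the control library and almost not in the CP5322 library. Of 13709 genes at 1 CPM or more in at least 1 library, 98.9% lay within 2-fold on the log2(CPM + 1) scale, and Pearson's r across these genes, which are not independent replicates, was 0.989. With CP5322, 32 genes were at least 2-fold higher and 113 at least 2-fold lower. With a minimum of 5 CPM in at least 1 library, 22 were higher and 30 lower. At 4-fold, again with the minimum of 1 CPM, the numbers were 2 and 34. In 20 simulated pairs of libraries with no changed gene, which carry counting noise and no culture effects, at most 1 gene was 2-fold higher and 0 were 2-fold lower.

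**Figure D1:**
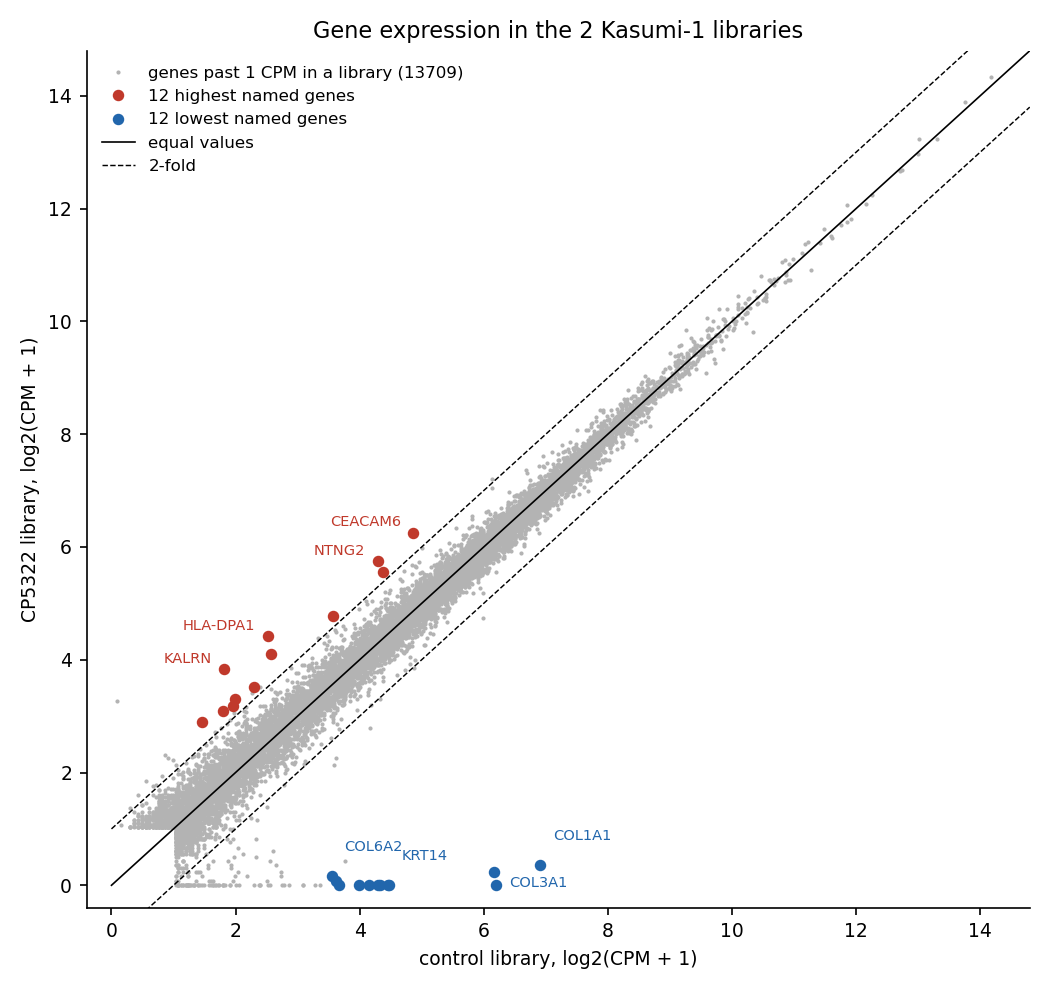
Each point is 1 gene, with log2(CPM + 1) in the control library on the x axis and in the CP5322 library on the y axis. The solid line marks equal values and the dashed lines 2-fold differences. The 12 highest named genes (red) lie just outside the upper line, while the 12 lowest (blue) lie along the bottom, at 5 counts or fewer with CP5322.

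The 12 lowest genes by the naming rule were 6 collagen genes, 4 keratin genes, FDCSP and IGFBP5. COL1A1, which encodes a chain of type I collagen (ENSG00000108821, chromosome 17, 50183289 to 50201632, GRCh38), had 5 counts with CP5322 and 2045 in control, a level 411-fold lower (176 to 1268). The partner chain COL1A2 had 3 and 1213 counts, 407-fold lower (139 to 1974). COL3A1 had 0 and 1240 counts, at least 416-fold lower when the 0 is taken as 3 counts. The type VI collagen genes COL6A1, COL6A2 and COL6A3 had 1, 2 and 0 counts against 192, 183 and 201. KRT14 and KRT5, the keratin pair of basal squamous epithelium, had 0 counts with CP5322 against 364 and 320, at least 122-fold and 107-fold lower. KRT6A had 0 against 359 and KRT13 0 against 287; KRT6A shares long stretches of sequence with its neighbouring copies, so its own count is uncertain. FDCSP, a secreted peptide of follicular dendritic cells and mucosal epithelia, had 0 against 327, and IGFBP5, a binding protein of insulin-like growth factors, 0 against 254.

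The fibroblast and endothelial markers and the epithelial markers, lists fixed before the data were examined, both stood apart. They hold some of the genes above, COL1A1, COL1A2 and COL3A1 in the first and KRT14 and KRT5 in the second. Of 14 fibroblast and endothelial markers past 1 CPM, 10 were at least 2-fold lower with CP5322 and 0 higher. Their median log2 fold was −1.98, or −2.85 with genes at 0 counts taken at their bound, below all 10000 random lists of like expression (percentile 0). DCN, a proteoglycan of connective tissue, had 0 counts against 149, and VWF, made by endothelium and megakaryocytes, 0 against 26. Of 8 epithelial markers, 4 were at least 2-fold lower (KRT14, KRT5, KRT19 and SFN), with a median of −1.01 and percentile 0. Without the 12 lowest named genes, a check added after seeing the data, the lists lay at percentiles 0 (11 genes, median −1.37) and 0.24 (6 genes, median −0.54). Marker lists of B cells, megakaryocytes, and T and NK cells did not stand apart. EPCAM, chosen after its values were seen, went the other way at 2400 counts against 1986, a ratio of 1.20 (1.13 to 1.28). With only genes of at least 5 CPM the epithelial list kept 5 members and its percentile was 17.4. Single genes of other lists had the same form. The calprotectin genes S100A8 and S100A9, of the late granulocyte list, had 0 counts against 73 and 159. The immunoglobulin light chain gene IGKC of the B cell list had 2 against 51 (while CD22 of that list had 45 against 8). CD9 had 0 against 22 and THY1 1 against 19.

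The imbalance was one-sided. In the control library, 125 genes had at least 10 counts while the CP5322 library had 0, and these genes held 6753 control counts, or 0.0395% of the library. The reverse held for 3 genes with 33 counts. Of the 113 genes at least 2-fold lower, 65 had 0 counts with CP5322, 91 had 5 or fewer, and 22 had more than 5. Leaving out genes annotated to matrix, collagen, keratin, epidermis, desmosome or immunoglobulin terms left 48 lower and 30 higher genes, a split chosen after seeing the data.

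With the pseudocount of 1 CPM, genes at least 2-fold higher were fewer than lower ones, though in FPKM there were 79 of each. Among the 12 highest and 12 lowest genes, the ratios of the higher ones lay closer to 1. KALRN, a guanine nucleotide exchange factor (ENSG00000160145, chromosome 3, 124080023 to 124726325), had 228 counts with CP5322 and 43 in control, a ratio of 5.27 (3.79 to 7.49). HLA-DPA1, which presents antigen in MHC class II, had 351 and 81 counts, a ratio of 4.31 (3.38 to 5.56), and HLA-DRA 278 and 85, a ratio of 3.25 (2.54 to 4.20). CIITA, the transactivator of class II genes and also among the 12 highest, had a ratio of 2.41 (2.03 to 2.87). HLA genes are similar to one another and vary between genomes, and how shared reads were counted is not given in the sources used here. CEACAM6, a cell adhesion molecule of granulocytes, had 1294 and 482 counts and a ratio of 2.67 (2.40 to 2.97). NTNG2, a netrin relative, had 909 and 318 counts and a ratio of 2.84 (2.50 to 3.24). RIPOR2, SCG2, C3, SYT11, INHBA and ABCA2 completed the 12, with ratios of 3.65, 2.96, 3.05, 2.82, 2.66 and 2.36. Outside the 12, CD74, the invariant chain of class II, had 2508 and 1188 counts and a ratio of 2.10 (1.96 to 2.25), and the B cell lectin gene CD22, at lower counts of 45 and 8, a ratio of 5.59 (2.61 to 13.7).

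Of 46 gene lists fixed before the data were examined, the median log2 fold of 3 lay over percentile 99 of the random lists and that of 9 under percentile 1. As many random lists would give 0.92 outside these percentiles. That number is nominal, since some lists share genes, genes of a list may vary together, and 2 lists had too few members for a call. The percentile describes these 2 libraries and not the treatment in general. Among all genes past 1 CPM, 20.9% had a counting interval wholly below a ratio of 1 and 18.4% wholly above, which is the background for the numbers of such members given per list. Apart from the marker lists of other cell types, the list medians lay between −0.34 and 0.30, so most list differences were well under 2-fold.

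**Figure D2:**
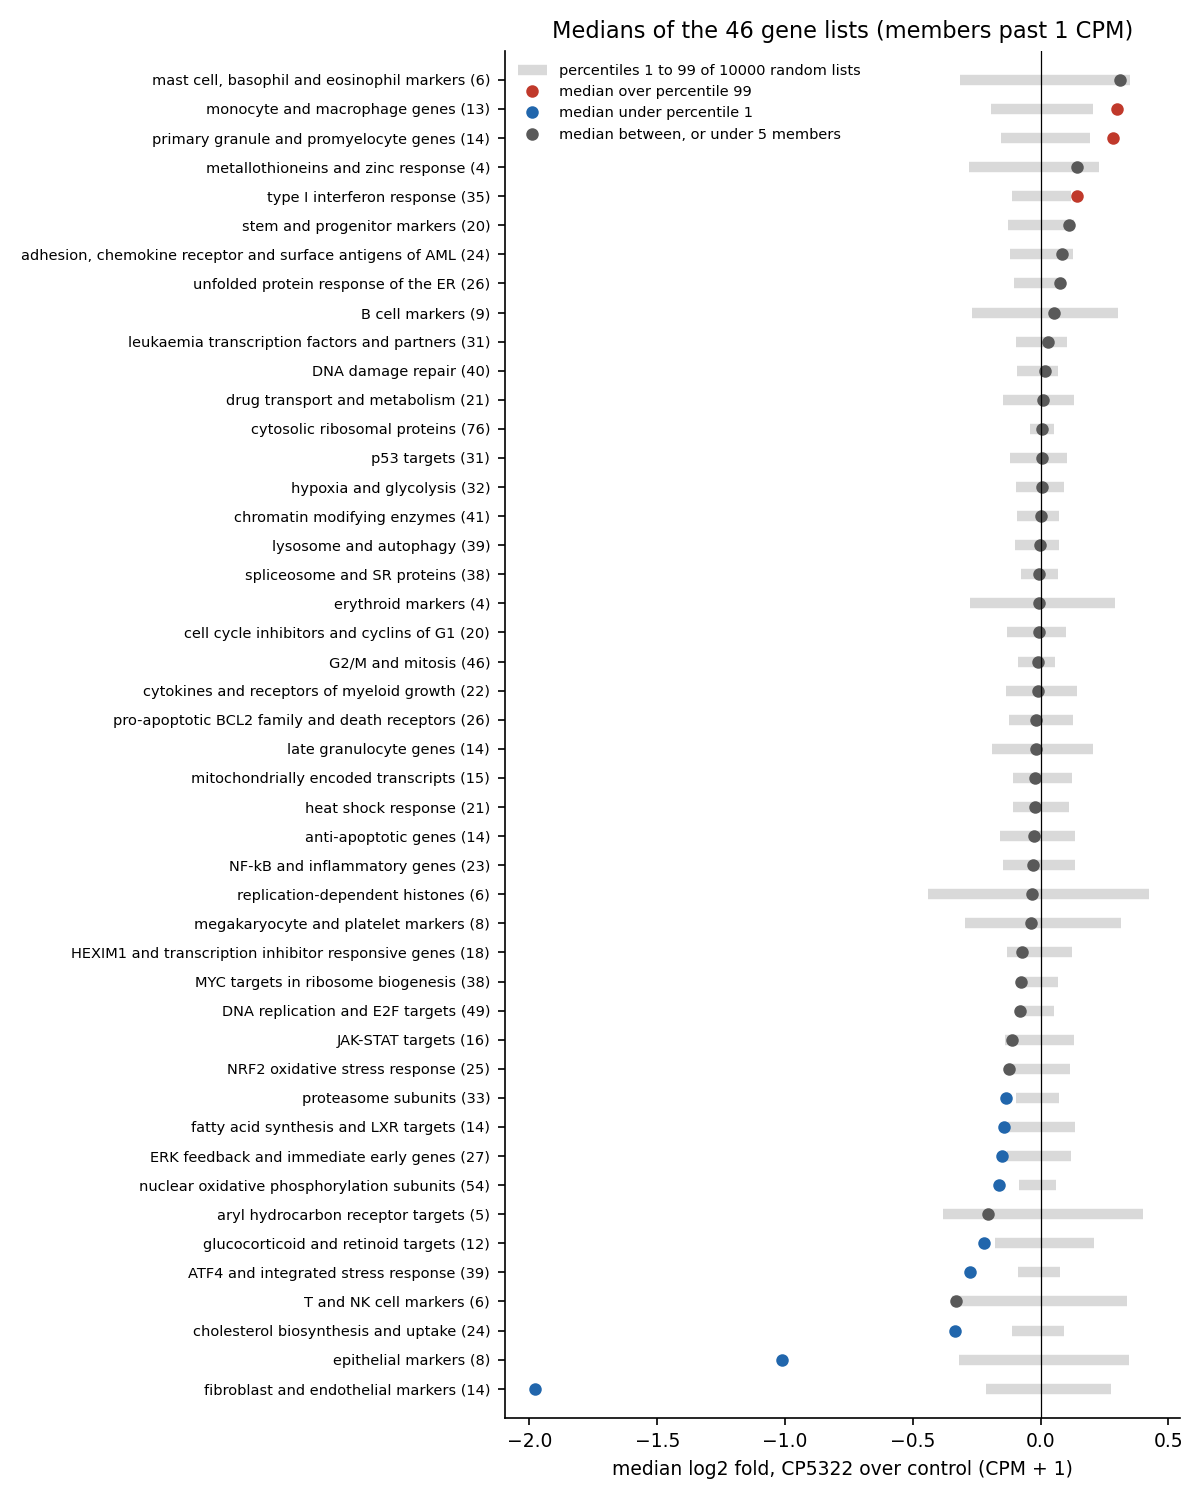
Points give the median log2 fold (CP5322 over control, CPM + 1) of each of 46 gene lists, with the number of members past 1 CPM in brackets, and grey bars span percentiles 1 to 99 of 10000 random lists of the same size and like expression. The 3 lists in red lie to the right of their bars and the 9 in blue to the left, the fibroblast and endothelial markers farthest out at −1.98.

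Genes of cholesterol synthesis and uptake were lower as a group. All but 1 of the 24 members had a log2 fold below 0, 20 had a counting interval wholly below a ratio of 1, and the median of −0.34 lay at percentile 0. LSS, lanosterol synthase, had 1090 counts against 1700, a ratio of 0.638 (0.590 to 0.688). ACAT2 had a ratio of 0.716 (0.647 to 0.793), and CYP51A1, with 18 and 38 counts, 0.471 (0.253 to 0.846). The list of fatty acid synthesis and LXR targets had a median of −0.14 over 14 genes (percentile 0.49), and 8 had an interval below 1. FASN, fatty acid synthase, had 15474 counts against 22213, a ratio of 0.693 (0.679 to 0.707), and the desaturases SCD and FADS2 had ratios of 0.705 (0.687 to 0.724) and 0.688 (0.663 to 0.714). The other 6 members had intervals that included 1, and this list lost its place under percentile 1 with no expression minimum (5.78) or with unmatched random lists (2.62).

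The list of ATF4 and integrated stress response genes, which serve amino acid synthesis, transport and tRNA charging, had a median of −0.28 at percentile 0. Of 39 members, 28 had an interval below 1 and 2 above. SLC7A11, the cystine transporter, had 140 counts against 294, a ratio of 0.474 (0.384 to 0.581), and ASNS, asparagine synthetase, 422 against 705, a ratio of 0.595 (0.526 to 0.673). SLC7A5, a transporter of large neutral amino acids, had a ratio of 0.677 (0.650 to 0.704). CTH, which makes cysteine from cystathionine, went the other way with 722 counts against 414, a ratio of 1.73 (1.53 to 1.96).

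Nuclear genes of oxidative phosphorylation had a median of −0.16 over 54 members (percentile 0), and 34 had an interval below 1 against 2 above. NDUFS8 of complex I had 946 counts against 1338, a ratio of 0.703 (0.646 to 0.765), and ATP5G3 of the ATP synthase 0.746 (0.712 to 0.781), while NDUFV2, at 57 and 28 counts, had 2.02 (1.27 to 3.31). Transcripts encoded in the mitochondrial genome did not stand apart, at a median of −0.02 and percentile 24.6, and made up 7.75% of counts with CP5322 and 7.48% in control. Proteasome subunits had a median of −0.14 (percentile 0.05), with 19 of 33 intervals below 1, among them PSMB6 at 0.781 (0.705 to 0.866) and PSMB5 at 0.808 (0.749 to 0.871). ERK feedback and immediate early genes had a median of −0.15 (percentile 0.31), with 12 of 27 intervals below 1 and 1 above, led by JUND at 0.637 (0.582 to 0.698) and KLF6 at 0.674 (0.598 to 0.759). This list lay at percentile 1.30 with a pseudocount of 5. Glucocorticoid and retinoid targets had a median of −0.22 over 12 genes (percentile 0.24), of which 4 had an interval below 1 and 2 above, with SGK1 at 0.675 (0.559 to 0.812) and TSC22D3 at 0.726 (0.636 to 0.828) but CYP26A1 at 1.56 (1.15 to 2.14), and lay at 1.12 in FPKM. Each of these lower lists was measured against the same control library that held the epithelial and stromal transcripts.

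The primary granule, monocyte and type I interferon lists were higher with CP5322, while late granulocyte genes and myeloid cytokines and receptors did not stand apart. Primary granule and promyelocyte genes had a median of 0.28 over 14 genes (percentile 99.98), of which 8 had an interval above 1 and 3 below. RNASE2, eosinophil-derived neurotoxin, had 398 counts against 211, a ratio of 1.88 (1.58 to 2.23), and BPI, a bactericidal granule protein, 57 against 29, a ratio of 1.95 (1.23 to 3.17). RNASE3 had 23 and 9 counts and a ratio of 2.54 (1.13 to 6.24). ELANE, neutrophil elastase, had 13 against 31, a ratio of 0.417 (0.200 to 0.820). MPO, myeloperoxidase, the most counted member and chosen after its values were seen, was also lower, at 33072 counts against 42375 and a ratio of 0.776 (0.765 to 0.787). The summed counts of the list, 60120 and 64366, therefore went against its median. Monocyte and macrophage genes had a median of 0.30 over 13 genes (percentile 99.94), with 6 intervals above 1 and 2 below. The 3 members at least 2-fold higher were HLA-DRA, CD74 and CIITA, which serve antigen presentation, while CSF1R, the receptor of macrophage colony-stimulating factor, had 44 counts against 61, a ratio of 0.717 (0.475 to 1.07), and VCAN, a proteoglycan of monocytes and connective tissue, 0.467 (0.340 to 0.636). CD14 had 2 and 3 counts. With no expression minimum this list lay at percentile 80.5, and with a pseudocount of 5 at 96.4.

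Type I interferon response genes had a median of 0.14 over 35 genes (percentile 99.73), with 13 intervals above 1 and 4 below, and lay at 98.3 with no expression minimum. IFIT2, IFIT3, RSAD2 and OASL, antiviral effectors induced by interferon, had ratios of 1.78 (1.5 to 2.11), 1.57 (1.35 to 1.82), 1.65 (1.37 to 2.00) and 1.77 (1.28 to 2.48). The 4 with an interval wholly below 1 were IRF7 and the membrane proteins IFITM1, IFITM2 and IFITM3, named after their values were seen. IFITM3 had 2479 counts against 3265, a ratio of 0.755 (0.716 to 0.796). The higher lists, like the lower ones, rest on a control library with transcripts of other cell types.

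**Figure D3:**
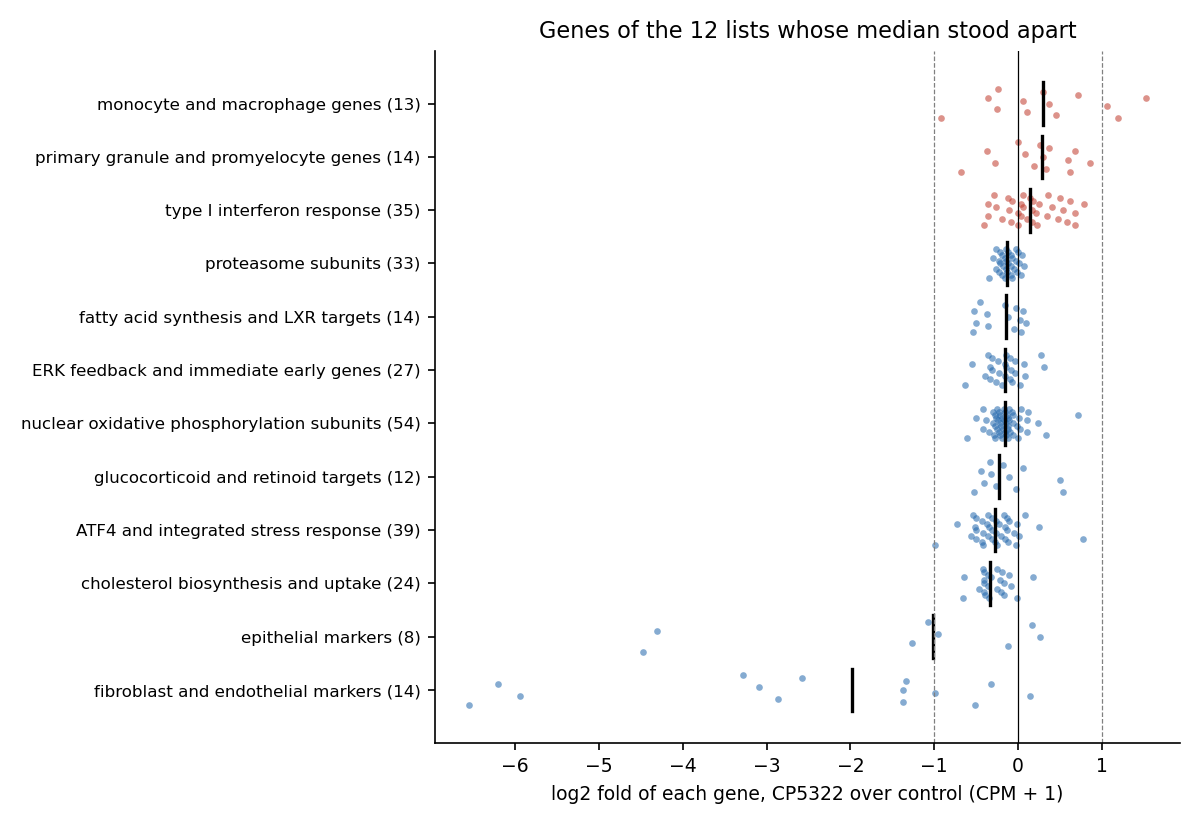
Each point is the log2 fold (CP5322 over control, CPM + 1) of 1 gene past 1 CPM in the 12 lists whose median stood apart, red for higher and blue for lower medians. Black bars mark medians and dashed lines 2-fold. Most points lie within 2-fold, except collagen, keratin and other stromal or epithelial genes on the left and 3 antigen presentation genes on the right.

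Genes tied to the fusion and to the progenitor state of this line were examined whatever their values. RUNX1 had 7768 counts with CP5322 and 6379 in control, a ratio of 1.21 (1.17 to 1.25), and RUNX1T1 5161 and 3828, a ratio of 1.34 (1.29 to 1.40). Gene counts do not separate the fusion transcript from the normal ones. CD34, a marker of progenitors, had 15870 and 10480 counts and a ratio of 1.51 (1.47 to 1.54), and the receptor gene KIT 1.15 (1.13 to 1.16). MYC had a ratio of 0.938 (0.915 to 0.962), and ITGAM, a marker of mature myeloid cells, 1.04 (0.786 to 1.39). CDKN1A, the cell cycle inhibitor p21, had 634 and 367 counts and a ratio of 1.72 (1.51 to 1.96), although the p53 target list did not stand apart (percentile 61.0) and MDM2, also a p53 target, had 0.781 (0.718 to 0.849). The transcription factor list lay at percentile 78.2, with ID1 lower at 231 against 486 counts, a ratio of 0.473 (0.402 to 0.554), and GFI1B higher at 67 against 28. Stem and progenitor markers lay at percentile 97.6.

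Lists of proliferation and death did not stand apart at the set thresholds. DNA replication and E2F targets came close, with a median of −0.08 at percentile 1.02, 23 of 49 intervals below 1 and 2 above. MYC targets in ribosome biogenesis lay at percentile 2.31, G2/M and mitosis genes at 61.2, G1 cyclins and inhibitors at 55.4, and replication-dependent histones at 38.5. Pro-apoptotic genes lay at percentile 38.2 and anti-apoptotic genes at 41.2. In these lists BCL2 had 4607 counts against 3068, a ratio of 1.49 (1.43 to 1.56), and BCL2L11, which encodes BIM, 1.51 (1.32 to 1.74). DNA damage repair genes lay at percentile 82.7.

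Stress and signalling lists between the thresholds included NRF2 targets (percentile 1.03), JAK-STAT targets (3.2), aryl hydrocarbon receptor targets (7.84), genes responsive to transcription inhibitors (11.8), heat shock genes (28.8), NF-kB and inflammatory genes (34.5), hypoxia and glycolysis genes (58.0) and unfolded protein response genes (97.3). Drug transport genes lay at 60.4, lysosome and autophagy genes at 61.2, chromatin enzymes at 61.5, spliceosome genes at 46.7 and cytosolic ribosomal proteins at 49.8. Among lineage lists, late granulocyte genes lay at 38.4, myeloid cytokines and receptors at 40.4, surface antigens of acute myeloid leukaemia at 92.8, megakaryocyte markers at 35.2, mast cell, basophil and eosinophil markers at 98.2, B cell markers at 59.6, and T and NK cell markers at 1.32. Metallothioneins and erythroid markers each had 4 members past 1 CPM, too few for a call.

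In the authors' deposited table, 275 genes were marked significantly higher and 412 lower, at an adjusted p under 0.05 and at least 2-fold. That test compares these 2 libraries, not the conditions. In the authors' deposited table, 105 of the higher and 205 of the lower genes were under 1 CPM in both libraries. All 32 and 113 genes that were 2-fold different here were marked there. The number of 2-fold genes rests on the pseudocount of 1 CPM, with 198 higher and 226 lower at 0.1, and 8 and 24 at 5. In FPKM with a pseudocount of 1 there were 79 of each.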

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

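Random lists matched on GC content and length, the 2 added counts of genes, and the marker lists without the 12 lowest genes (both still under percentile 1) were chosen after seeing the data. No paired analysis was possible because each condition has 1 library. Of the 12 lists that stood apart, 6 did so under every alternative run, namely primary granule genes, ATF4 and integrated stress response, cholesterol, nuclear oxidative phosphorylation, proteasome, and fibroblast and endothelial markers. Of 413 pairs of list and alternative, 24 changed a call, and the causes were not tested. None of the 12 lists that stood apart reversed. Reversal was not assessed for the lists that did not stand apart. Monocyte genes fell back to percentile 96.4 with a pseudocount of 5 and 80.5 with no minimum. Interferon genes lay at 98.3 with no minimum. Fatty acid genes lay at 5.78 with no minimum, 2.62 unmatched, 1.20 in FPKM and 1.51 with GC and length matched. ERK genes lay at 1.30 with a pseudocount of 5 and 1.6 with GC and length matched. Glucocorticoid and retinoid targets lay at 1.12 in FPKM, and epithelial markers at 17.4 with a minimum of 5 CPM, which leaves 5 members. Under an alternative, 8 more lists stood apart. DNA replication genes reached 0.975 with a pseudocount of 0.1. NRF2 targets reached 0.940 with a minimum of 5 CPM, 0.360 with none and 0.895 with 10 bins. T and NK markers reached 0.160 unmatched, 0.710 with 10 bins and 0.480 with GC and length matched. With no minimum, however, T and NK markers lay at 70.1 with a median of 0.04. Stem and progenitor markers reached 99.95 with a minimum of 5 CPM and percentile 100 in FPKM, where histones reached 0.4 and surface antigens 99.46. Mast cell, basophil and eosinophil markers reached 99.61 unmatched, and ribosomal proteins 99.72 with GC and length matched.

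The counts of 2-fold genes, 32 higher and 113 lower, were 198 and 226 with a pseudocount of 0.1, and 8 and 24 with 5. In FPKM there were 79 higher, and 79 lower. A minimum of 5 CPM left 22 higher and 30 lower, and leaving out matrix, keratin and immunoglobulin annotation 30 and 48. Requiring over 5 counts in both libraries left 30 and 22, a filter that by its construction removes the 91 lower genes with 5 counts or fewer with CP5322 and so says nothing about direction. Each scaling gave 32 and 113. At an adjusted p under 0.01, the authors' deposited table held 118 higher and 249 lower genes in place of 275 and 412. Of 784 log2 folds of named genes under an alternative, 772 moved by less than their counting error, which has no upper end for genes at 0 counts. The other 12 moved more, each with another pseudocount. That 0 reversed was fixed in advance, since a pseudocount keeps the sign of a fold and the scalings were nearly equal.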

Other observations

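The gene ontology terms and the tests in this part were chosen after the main results had been seen. Of 1841 terms, 31 had a median over percentile 99 and 70 under percentile 1. As many random lists would give 18.4 at each end, a nominal number since terms share genes. With random lists matched also on GC content and length, 29 and 57 terms kept their side. The lowest medians were those of peptide cross-linking (−1.01), hemidesmosome assembly (−0.56), desmosome (−0.35), collagen catabolic process (−0.34) and keratin filament (−0.30), at percentiles of 0 to 0.02 under both matchings. These terms hold 6, 3, 7, 11 and 7 genes at least 2-fold lower, so part of the 70 low terms reflects the epithelial and stromal transcripts. Several terms of mitochondrial translation were also lower, as were the nuclear oxidative phosphorylation genes, but the term mitochondrial ribosome (22 genes) went from percentile 0.19 to 1.48 once GC content and length were matched. Mitochondrial translational elongation had a median log2 fold of −0.17 over 79 genes, 0 of which were 2-fold different, at percentile 0 under both matchings. Mitochondrial translation (29 genes) had −0.19 at percentile 0.03. Folic acid metabolic process, 13 genes of one-carbon transfer, had −0.23 at percentile 0.03, and iron-sulfur cluster assembly −0.19 at percentile 0.32.

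At the other end, the highest median, 0.49 over 14 genes with 3 of them 2-fold higher, was that of the term for the lumenal side of the endoplasmic reticulum membrane, which includes MHC genes, at percentile 100 under both matchings. It was followed by voltage-gated calcium channel complex (0.29, 12 genes), protein K29-linked ubiquitination (0.29, 11 genes), establishment of planar polarity (0.28, 10 genes) and negative regulation of interleukin-6 production (0.26, 17 genes, percentile 100). With smaller medians, MHC class I peptide presentation had 0.16 over 19 genes at percentile 99.98, and type I interferon signaling 0.145 over 40 genes at percentile 100. The 4 genes annotated to the MHC class II complex and past 1 CPM were all higher with CP5322, with ratios of 4.31 for HLA-DPA1, 3.25 for HLA-DRA, 2.10 for CD74 and 2.07 (1.47 to 2.93) for HLA-DMA. The highest log2 fold of all genes past 1 CPM, outside the naming rule and singled out after its value was seen, was that of FP671120.1, a long non-coding RNA with 148 counts with CP5322 and 1 in control, a ratio of 147 (26.0 to 5852).

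Collagen, keratin and other epithelial and stromal transcripts were in the control library (COL1A1 at 119.6 and KRT14 at 21.3 CPM) and nearly absent with CP5322, and total counts in a ratio of 1.006 argue against a difference in depth. RNA or reads of another tissue in the control library may account for the pattern but stay open: in marker lists written after the pattern was seen, 2 of 5 cell kinds of a mucosa or skin and 0 of 4 kinds from other organs were at least 5 times higher in control once every gene at least 2-fold lower was left out, which took away 19 of 22 squamous and 14 of 16 fibroblast genes, so that these numbers neither show nor exclude it. Squamous epithelium had 0 counts against 41 over the 3 genes left (at least 13.7 times higher in control), antibody-secreting cells 5.28 times (2.45 to 13.0, 4 genes), fibroblasts 2.45 times (1.58 to 3.88, 2 genes, 1 of them past 1 CPM with CP5322), endothelium 1.5 times (1.26 to 1.80, 7 genes, 2 of them past 1 CPM) and smooth muscle 0.883 times (0.764 to 1.02, 6 genes, 5 of them past 1 CPM). Hepatocyte, neuron, lung and skeletal muscle genes stood at 1.12, 0.877, 1.10 and 0.835 times. Loss of these transcripts from treated cells cannot be told apart from this with 1 control library, where the whole squamous and fibroblast lists, the 12 lowest genes included, kept 0.631% of their control level with CP5322.

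The lower lists may reflect CP5322 or a difference between these cultures or libraries. Bias by GC content or gene length as the whole cause is argued against for 5 of them, whose percentiles among lists matched on expression, GC content and length were 0 for ATF4 and integrated stress response, 0 for cholesterol, 0 for nuclear oxidative phosphorylation, 0.105 for proteasome and 0.28 for glucocorticoid and retinoid targets. Matching ended the call of fatty acid and LXR targets (1.51) and ERK feedback genes (1.6), although the distance of their medians from the random median shrank only from −0.14 to −0.12 and from −0.15 to −0.11, with percentile 1 of the matched lists at −0.15 and −0.16, so the bias is neither shown nor excluded for these lists. Reads of another tissue stay open for the cholesterol list, since no profile of the source is at hand: the list had 522 CPM more in control, against 395 CPM in all genes at 0 counts with CP5322 and at least 10 in control. The effect of the compound was not tested, as 1 library per condition holds no spread between cultures.

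For the higher lists, GC content and length as the whole cause are argued against, as far as matching in 4 bins each goes. After it, the percentiles were 99.99 for primary granule, 99.89 for monocyte and 99.83 for interferon genes. An effect of CP5322 on these genes stays open as a hypothesis, as does a difference between 2 cultures of the line, and neither was tested.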
